A study of Mus musculus with 12 samples.

How the data were processed

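Total RNA of RAW264.7 cells, 50 ng per array per the labels' protocols, was labelled with Cy3 and hybridised to 1-colour Agilent mouse expression arrays, 1 array per sample and 12 in all. Cells grew in medium with 10% serum, per the labels. Per the file headers, spots were quantified with Agilent Feature Extraction 10.7.3.1, which subtracts the background and gives a processed intensity per spot on a linear scale, with flags for signals well above background, saturation and outliers. The deposited intensity values are not normalized between arrays. The authors' deposited value table holds 62973 spots per array and matches the processed intensity of each array within 0.005, so its scale is linear and it is not centred, and its column medians lie between 12.97 and 18.4. What else the authors did is not given in the sources used here. The headers name the mouse build mm9 for probe positions. The reference used here is of another build and served for names only, so whether a probe lies in an exon or a UTR was not analysed here.

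Groups came from the labels: control, FABP4, palmitic acid, and palmitic acid with FABP4, with 3 arrays each. Control spots and outlier spots were left out (10 array values of tested genes), spots of a probe were averaged, and 55681 probes with 34797 gene names remained. Values were log2 of the processed intensity minus each array's 75th percentile of it over all non-control spots. Since under 50% of the spots were well above background on each array, the percentile over probes detected on all arrays (21740) was added as an alternative after seeing the data. A probe entered the tests if it was well above background on all 3 arrays of at least 1 group (23911 probes), and the brightest such probe stood for its gene, which left 17596 genes. Gene names are those of the array's design, which can be old. Accessions of 27235 probes (48.91%) matched the reference table, and 12199 tested genes have a current symbol from it. Where a called gene had further probes, 432 of 539 had the same sign for palmitic acid without FABP4, and 19 had the opposite sign at an unadjusted p under 0.05, among them probes of Stard4 and Acss2. For palmitic acid with FABP4 these counts were 196 of 231, and 3.

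A linear model with 4 group means was fitted to all 12 arrays with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with version 1.17.8 of the data.table package. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. The contrasts were FABP4 without and with palmitic acid, palmitic acid without and with FABP4, their interaction, and the average effect of FABP4. Where a probe was not well above background on any array of a group, the change is a bound ("at least"): the brighter group's mean against the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

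Lists and naming were fixed before the data were examined. The 27 gene lists (582 genes, 1 not on the array, 9 found under older names) cover NF-kB response, interferon response, inflammasome, alternative activation, macrophage identity, osteoclast, dendritic cell, neutrophil, fibroblast, adipocyte, fatty acid oxidation and PPAR targets, fatty acid binding and transport, lipid droplet, cholesterol biosynthesis, fatty acid synthesis, LXR targets and efflux, scavenger receptors, unfolded protein response, ATF4 response, NRF2, heat shock, immediate-early and MAPK, glycolysis and hypoxia, oxidative phosphorylation, lysosome, cell cycle, and p53 targets. A few genes, such as Plin2 and Cd36, belong to more than 1 list. The 24 lists with at least 5 tested members were tested on 17586 genes complete on all arrays with camera in limma at a preset correlation of 0.01, adjusted over the lists of a contrast. Camera with a correlation estimated per list and fry were alternatives. The genes named per comparison are Fabp4, then the 6 largest rises and 6 largest falls among called genes whose groups do not overlap and which have an official symbol, or the 12 smallest p-values where fewer pass. To these come the 4 smallest p-values in each list that passed or had at least 3 members called, and the 3 smallest in the NF-kB, fatty acid oxidation and cholesterol biosynthesis lists whatever their test. For the interaction they are the 6 smallest p-values. Not every gene that the rule names is reported here.

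Alternatives were quantile normalization, the median over tested genes, normexp on the mean and background signals (offset 50) with the 75th percentile or with quantile normalization, the deposited value table, no filter on dim probes, only probes above background on all 12 arrays, the mean of a gene's probes or every probe, and slide as a fixed or random block. Further ones were the arrays of 1 slide, a replicate block, only the groups compared, trended and robust moderation, a minimum of 1 on the log2 fold change, and leaving out each array in turn. No scaling between arrays and list tests within slide 2 were added after seeing the data. The limma fit without a block, and camera at the preset correlation, were tested on simulated data with the real genes' levels and spread. With 200 of 17596 genes changed, between 1.7% and 10.7% of the calls were false wherever calls were made. The interaction at 1.25-fold gave 0 calls, so it has no such share. The alternatives were not simulated. Simulated genes varied independently and held no difference between slides, so the shares recovered, given below, leave out the slides. A simulated list of 25 genes shifted by 0.3 on the log2 scale was found, and 0 unchanged lists were called. Since the simulated genes were independent, this cannot show how camera treats lists whose members vary together.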

Results

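Gene expression was measured in RAW264.7 cells, a mouse macrophage line, after 24 h with or without added recombinant FABP4 and with or without palmitic acid. FABP4, also called aP2, is a fatty acid binding protein of adipocytes and macrophages, and palmitic acid is a common saturated fatty acid. FABP4 was given at 200 nM and palmitic acid at 0.2 mM, in medium holding 0.5% BSA free of fatty acids. The 4 groups were control, FABP4, palmitic acid, and palmitic acid with FABP4, with 3 arrays each. The labels do not say that the arrays of a group came from separate cultures, so all p-values measure only the spread between these samples, which may be technical. Each of the 12 arrays held 59305 non-control spots. Between 42.8% and 46.7% of them were well above background, 0 were saturated, and the 75th percentile of the signal lay between 250.1 and 315 intensity units. After filtering, 17596 genes were tested, and their number of arrays limits the precision: the median SE of a log2 fold change was 0.08, and the 95% confidence interval reached 0.19 to each side. Unless another error is named, values below are log2 fold changes ± SE from limma with n = 3 arrays per group, and adjusted p-values are Benjamini-Hochberg over all genes tested.

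The arrays lay on 2 slides. Slide 1 held the 3 control arrays and FABP4 array 1, and slide 2 held FABP4 arrays 2 and 3 and all 6 arrays with palmitic acid. Median signals were 15.5 to 16.3 on slide 1 and 16.9 to 21.7 on slide 2. The comparison of FABP4 with palmitic acid therefore lay within slide 2, whereas palmitic acid without FABP4 was compared entirely across the slides. On slide 2, FABP4 arrays 2 and 3 lay in row 1 and the 3 arrays of palmitic acid with FABP4 in row 2. Palmitic acid and row therefore cannot be told apart between these groups within slide 2. Palmitic acid arrays 1 and 2 lay in row 1 as well, and palmitic acid array 3 in row 2. Among the arrays with palmitic acid, FABP4 and row were thus largely mixed. On the first principal component, with 31.7% of the variance, FABP4 array 1 scored -27.7 near the controls at -22.0 to -15.4. FABP4 arrays 2 and 3 scored 2.6 and 3.8, nearer to the arrays with palmitic acid at 9.4 to 18.8. On the second component, with 10.9% of the variance, FABP4 arrays 2 and 3 scored 20.6 and 19.3, while the other arrays lay between -8.0 and 1.3.

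**Figure D1:**
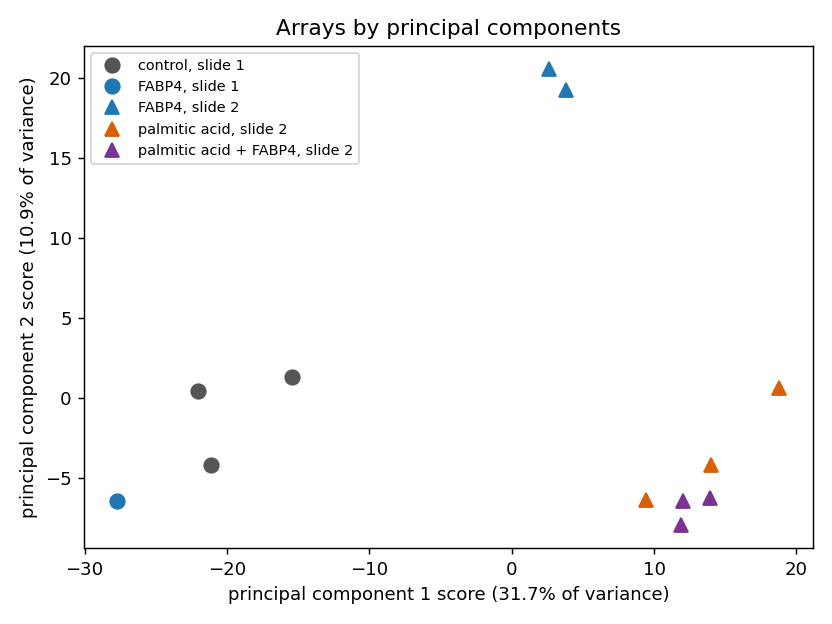
Scores of the 12 arrays on principal component 1 (x axis, 31.7% of the variance) and component 2 (y axis, 10.9%), with color for the group, circles for slide 1 and triangles for slide 2. FABP4 array 1 lies near the controls of its slide, and FABP4 arrays 2 and 3 stand apart from every other array on component 2.

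Palmitic acid without FABP4 raised Plin2, Cpt1a and Fabp4, and lowered the cholesterol exporters Abca1 and Abcg1 and the fatty acid synthesis genes Acaca, Fasn and Scd2. This comparison asks what the fatty acid does to macrophages that receive no added FABP4, and it also sets slide 2 against slide 1. Plin2, which encodes a coat protein of lipid droplets, rose 2.68-fold (1.42 ± 0.06, adjusted p = 1.63e-06). Cpt1a, the carnitine palmitoyltransferase that admits long-chain fatty acids to mitochondria, rose 2.59-fold (1.37 ± 0.06, adjusted p = 1.59e-06). Fabp4 itself rose 1.47-fold (0.56 ± 0.07, adjusted p = 0.00313). Abca1 and Abcg1, which export cholesterol from macrophages, fell by 0.98 ± 0.08 and 0.87 ± 0.07 on the log2 scale (adjusted p = 1.57e-04 and 1.56e-04). In the files' mm9 coordinates the probes lie on chromosome 4 at 86302847 to 86302906 for Plin2, on chromosome 19 at 3385374 to 3385433 for Cpt1a, on chromosome 3 at 10204452 to 10204511 for Fabp4, on chromosome 4 at 53043944 to 53044003 for Abca1 and on chromosome 17 at 31252580 to 31252639 for Abcg1. With the slide as a fixed block the values of these 5 genes were 1.51, 1.45, 0.73, -0.80 and -0.74, with adjusted p = 3.76e-04, 3.39e-04, 0.0334, 0.0275 and 0.0250. Hilpda, which encodes a lipid droplet protein and is induced by fatty acids and hypoxia, rose by 1.44 ± 0.05 (adjusted p = 6.35e-07), a gene outside the naming rule here and chosen after its values were seen.

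**Figure D2:**
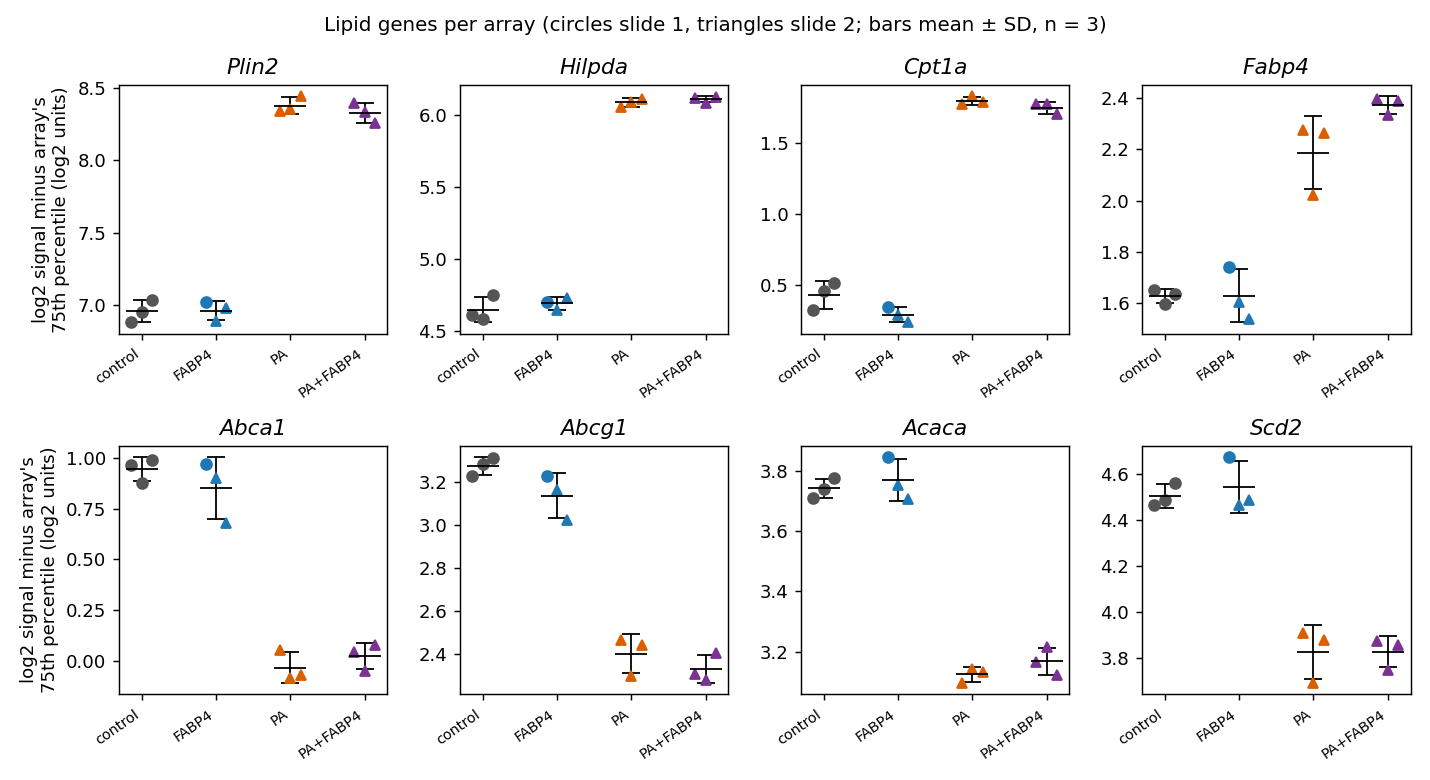
Log2 signal minus each array's 75th percentile (y axis, log2 units) for 8 lipid genes in the 4 groups (x axis), with a point per array, circles for slide 1, triangles for slide 2, and bars for the mean ± SD of 3 arrays. Plin2 lies between 6.88 and 7.04 on the arrays without palmitic acid and between 8.26 and 8.44 on those with it, and each y axis has its own range.

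In this comparison limma called 1515 genes, 858 up and 657 down, of which 69 rose and 3 fell by more than 1 on the log2 scale. Dok7, an adaptor protein of a muscle receptor kinase, rose 3.55-fold (1.83 ± 0.07, adjusted p = 6.35e-07), and Adm, which encodes the vasodilator peptide adrenomedullin, rose 3.34-fold (1.74 ± 0.20, adjusted p = 0.0014) from controls of which 2 arrays were well above background. Pilra, an inhibitory receptor of myeloid cells, fell by 1.05 ± 0.06 on the brightest probe and had -0.96, -1.10 and 0.17 on its other probes (unadjusted p = 1e-05, 3.24e-04 and 0.425), and the transcription factor Klf2 and the prostaglandin receptor Ptger2 fell by 0.87 ± 0.14 and 0.83 ± 0.10. Among the other genes with the largest changes, Catsperg2 rose at least 3.70-fold and Faah at least 1.81-fold from controls not well above background on any array. Their calls ended without control array 3 for Catsperg2 (adjusted p = 0.116) and without palmitic acid array 2 for Faah (adjusted p = 0.0893). The calls of Sox14, Vwf and Ncrna00085 ended without palmitic acid array 2, control array 1 and control array 1 (adjusted p = 0.148, 0.0788 and 0.105), and these 5 genes' calls ended without other arrays as well. Of the 70 genes named by rule that passed, 45 passed whichever array was left out.

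No slide holds both groups of this comparison, and a fit with the slide as a block takes the slide difference from the FABP4 group, which has 1 array on slide 1. With the slide as a fixed block 138 genes passed (78 up, 60 down), 78 of them among the 1515, and 17 of the 70 named calls held. These were Fabp4, Dok7, Pilra, Abca1, Abcg1, Igtp, Cx3cr1, Dcstamp, Cpt1a, Plin2, Acaca, Dnajb9, Atf3, Ndrg1, Bnip3, Plk2 and Mdm2, so every other call named by rule without FABP4 ended in that fit. All 53 ended calls kept their sign, at a median of 0.793 of their size (0.045 to 1.5), while the SE rose by a median factor of 1.72, so many ended at a similar size with a wider error. Lcn2 had -0.51 ± 0.12 with the block, Ifnb1 0.53 ± 0.12, Csf2 -0.53 ± 0.12, Srebf2 0.47 ± 0.12 and Car2 0.56 ± 0.11, whereas Dusp6 had -0.16 ± 0.10 and Itgam -0.15 ± 0.08. With the slide as a random block 191 genes passed (135 up, 56 down), all of them among the 1515, and 32 of the named calls held, those 17 and 15 more, including Adm, Ptger2, Csf2, Lcn2, Ifnb1, Scd2, Srebf2, Car2, Atp6v0d2, Gdf15 and Gpnmb. Without control array 1 the count was 655, without control array 3 it was 677, without palmitic acid arrays 1, 2 and 3 it was 928, 728 and 905, and without FABP4 array 1 it was 2716. With no scaling between arrays, an alternative chosen after seeing the data, the median over all genes moved from 5e-04 to 0.17 and the calls to 2945 up and 110 down, so rises and falls are relative to each array's 75th percentile. With the slide as a fixed block the median over all genes was 0.04, against which the list medians of that fit are to be read. Any departure of FABP4 array 1 from the controls adds directly to the palmitic acid effects of that fit.

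Among the lipid lists without FABP4, fatty acid synthesis and desaturation genes fell as a group by camera (adjusted p = 9.25e-06), with adjusted p = 0.235 with an estimated correlation. Of 14 tested, 6 fell, 0 rose and 8 did not pass, and 8 fell adjusted over the list alone. Acaca and Fasn, the enzymes that make malonyl-CoA and palmitate, fell by 0.62 ± 0.05 and 0.74 ± 0.11, and the desaturase gene Scd2 fell by 0.68 ± 0.08 (adjusted p = 1.57e-04, 0.00467 and 0.00124). Their median was -0.29, and -0.21 with the slide as a block (adjusted p = 0.00104), and the call of Acaca held (adjusted p = 0.0238) while that of Fasn ended at -0.65 ± 0.20 (adjusted p = 0.167). Of 12 tested LXR targets and cholesterol efflux genes, 3 fell (Abca1, Abcg1 and Nr1h3) and 0 rose, as adjusted over the list alone, and the list did not pass (adjusted p = 0.0554, and 0.0941 with the slide as a block). Nr1h3, which encodes LXR alpha, fell by 0.24 ± 0.06 (adjusted p = 0.0451), with -0.09 on its other probe (unadjusted p = 0.199), and its call ended without each array except control array 2 and FABP4 array 1, at the highest without control array 3 (adjusted p = 0.148).

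Of 20 tested genes of fatty acid oxidation and PPAR targets, 2 rose (Cpt1a and Plin2) and 18 did not pass, with 3 rises adjusted over the list alone. The list did not pass (adjusted p = 0.294), but passed upward with the slide as a block (median 0.14, adjusted p = 0.00288). Lipid droplet and triglyceride genes gave 2 rises among 17 (Plin2 and Hilpda), also adjusted over the list alone, with adjusted p = 0.294 for the list, whose median was below 0 while its mean and test were above. Among 14 fatty acid binding and transport genes, Fabp4 and the heart type Fabp3 (0.54 ± 0.07, adjusted p = 0.00192) rose and 12 did not pass, likewise adjusted over the list alone, and the list gave adjusted p = 0.378. Of 24 cholesterol biosynthesis genes 3 rose and 2 fell, with 3 rises and 3 falls adjusted over the list alone. Srebf2, which encodes the main regulator of the pathway, rose by 0.48 ± 0.07 (adjusted p = 0.00356) on the brighter probe and had 0.03 on its other probe (unadjusted p = 0.609). That list gave adjusted p = 0.632 and passed upward with the slide as a block (median 0.18, adjusted p = 0.00395). FABP4 array 1 against the controls had a median of 0.12 for this list, which enters the fit with the block.

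Scavenger receptor and lipoprotein uptake genes rose as a group by camera in palmitic acid without FABP4 (adjusted p = 0.00857), with adjusted p = 0.245 with an estimated correlation. Of 15 tested 2 rose, 0 fell and 13 did not pass, with 6 rises adjusted over the list alone. The 2 were Cd68, a lysosomal glycoprotein of macrophages (0.26 ± 0.06, adjusted p = 0.0196), and Scarb2 (0.31 ± 0.07, adjusted p = 0.0288). Both calls ended without control array 1 (adjusted p = 0.0713 and 0.101) and without some other arrays of the groups compared. The list's median was 0.06, and 0.21 with the slide as a block (adjusted p = 0.00395). Lysosome genes gave 3 rises and 0 falls among 27, also adjusted over the list alone, and the list passed upward (median 0.10, adjusted p = 0.00478, and adjusted p = 0.317 with an estimated correlation). Its median was 0.17 with the slide as a block (adjusted p = 3.47e-04). Gpnmb, a membrane glycoprotein of lysosomes and phagosomes, rose by 0.52 ± 0.05 (adjusted p = 5.94e-04).

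Of 36 tested NF-kB response genes 1 rose, 5 fell and 30 did not pass, with 2 rises and 6 falls adjusted over the list alone. The cytokine gene Csf2 and the acute-phase genes Lcn2 and Saa3 fell by 0.59 ± 0.07, 0.46 ± 0.06 and 0.29 ± 0.05, whereas Csf3 rose by 0.31 ± 0.06. The list passed downward (median -0.06, adjusted p = 0.0389), with adjusted p = 0.471 with an estimated correlation, and its call ended with the slide as a block (median 0.02, adjusted p = 0.363). Of 35 interferon genes 4 rose and 1 fell, with 5 rises and 2 falls adjusted over the list alone, and Ifnb1, which encodes interferon beta, rose by 0.44 ± 0.07 (adjusted p = 0.00506). That list gave adjusted p = 0.543 and passed upward with the slide as a block (median 0.12, adjusted p = 3.47e-04). Among 22 macrophage identity genes 3 fell, with 4 falls adjusted over the list alone, including the fractalkine receptor gene Cx3cr1 by 0.63 ± 0.07 and the integrin gene Itgam by 0.34 ± 0.06 (list adjusted p = 0.178).

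Osteoclast genes, markers of another fate of this cell line, gave 7 rises and 2 falls among 13 without FABP4, with 8 rises and 3 falls adjusted over the list alone. Dcstamp, which encodes a cell fusion protein and is carried on the array as Tm7sf4, rose by 0.73 ± 0.06 (adjusted p = 2.2e-04), and the proton pump subunit gene Atp6v0d2 and the carbonic anhydrase gene Car2 rose by 0.56 ± 0.08 and 0.50 ± 0.06. The list passed upward (median 0.33, adjusted p = 0.00448), with adjusted p = 0.235 with an estimated correlation, and its median was 0.18 with the slide as a block (adjusted p = 0.0129). Among markers that fell in this list were Nfatc1, the transcription factor that drives osteoclast formation, by 0.54 ± 0.12, and the collagenase gene Mmp9 by 0.51 ± 0.12, both chosen after their values were seen. Alternative activation genes gave 2 rises and 2 falls among 12, with 4 and 3 adjusted over the list alone (adjusted p = 0.715 for the list), and Ccl17 fell by 0.49 ± 0.09. Of 12 inflammasome genes 1 rose (Pycard, chosen after its values were seen), with 2 rises adjusted over the list alone (adjusted p = 0.884), and of 9 dendritic cell genes 1 fell (Cd80, chosen likewise), also adjusted over the list alone (adjusted p = 0.715). Too few members were detected to test the lists for neutrophils (3, with 0 past the threshold), fibroblasts (3, with 0) and adipocytes (2, with 1 fall, of Retn). With the slide as a block the calls of Mmp9 and Retn ended at a similar size with a wider error (-0.49 ± 0.22 and -0.50 ± 0.19 against -0.51 ± 0.12 and -0.52 ± 0.10, adjusted p = 0.342 and 0.248). Those of Nfatc1 and Pycard ended at a smaller size (-0.20 ± 0.18 and 0.10 ± 0.14 against -0.54 ± 0.12 and 0.38 ± 0.10, adjusted p = 0.679 and 0.792), and that of Cd80 held (-1.08 ± 0.13, adjusted p = 0.0105).

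Glycolysis and hypoxia genes rose as a group by camera without FABP4 (adjusted p = 9.25e-06), with adjusted p = 0.272 with an estimated correlation. Of 30 tested 9 rose, 0 fell and 21 did not pass, with 13 rises and 1 fall adjusted over the list alone. Bnip3 and Ndrg1, targets of hypoxia signalling, rose by 1.14 ± 0.11 and 0.76 ± 0.06 (adjusted p = 6.71e-04 and 2.01e-04), and the angiogenic factor gene Vegfa by 0.41 ± 0.06 (adjusted p = 0.0051). The list's median was 0.11, and 0.19 with the slide as a block (adjusted p = 4.75e-04). Of 29 oxidative phosphorylation genes 0 passed, nor any adjusted over the list alone, with 4667 of all genes at an unadjusted p under 0.05 in limma, and the list gave adjusted p = 0.277.

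Of 21 unfolded protein response genes 3 rose and 0 fell, with 4 rises adjusted over the list alone, among them the chaperone cofactor gene Dnajb9 with 0.61 ± 0.07 (adjusted p = 0.00132). The list passed upward (median 0.07, adjusted p = 0.0294), with adjusted p = 0.471 with an estimated correlation and 3.47e-04 with the slide as a block, where the median was 0.16. ATF4 and amino acid response genes gave 4 rises and 1 fall among 32, with 4 and 2 adjusted over the list alone. The stress-induced genes Atf3, Ppp1r15a and Gdf15 rose by 0.56 ± 0.04, 0.57 ± 0.06 and 0.77 ± 0.13, and the amino acid transporter gene Slc3a2 by 0.47 ± 0.06, while the list gave adjusted p = 0.765 and a median below 0 with its mean above. NRF2 genes gave 2 rises among 20, with 3 adjusted over the list alone (adjusted p = 0.178), and heat shock genes 1 fall among 12, also adjusted over the list alone (adjusted p = 0.0998). Immediate-early and MAPK genes gave 2 rises and 3 falls among 19, with 2 and 6 adjusted over the list alone (adjusted p = 0.102), and the phosphatase genes Dusp2 and Dusp6 fell by 0.46 ± 0.05 and 0.44 ± 0.08.

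Cell cycle genes fell as a group by camera without FABP4 (adjusted p = 1.23e-06), with adjusted p = 0.317 with an estimated correlation. They gave 13 falls, 0 rises and 21 not passing among 34 tested, and 15 falls and 1 rise adjusted over the list alone. The mitotic genes Ccna2, Ccnb1, Cdc20 and Birc5 fell by 0.47 ± 0.07, 0.37 ± 0.06, 0.37 ± 0.06 and 0.39 ± 0.07, and the other probes of Ccnb1 had -0.16 and -0.20 (unadjusted p = 0.0591 and 0.0183). Their median was -0.21. In the fit with the slide as a block the median was -0.04 and the call ended (adjusted p = 0.204), as did that of Ccna2 at -0.24 ± 0.10 (adjusted p = 0.276). FABP4 array 1 against the controls had a median of 0.09 for this list, which enters that fit. Of 18 p53 target and apoptosis genes 2 rose and 2 fell, with 2 and 3 adjusted over the list alone (adjusted p = 0.624). The kinase gene Plk2 rose by 0.91 ± 0.08 and Mdm2, which encodes the ligase that degrades p53, by 0.38 ± 0.06, and both held with the slide as a block (1.11 and 0.59, adjusted p = 0.00614 and 0.0186).

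Palmitic acid in the presence of FABP4, compared with FABP4 alone, raised Cpt1a, Hilpda, Plin2 and Fabp4 and lowered Abca1, Abcg1, Acaca and Scd2. Cpt1a rose 2.76-fold (1.46 ± 0.06, adjusted p = 8.25e-07), Hilpda 2.67-fold (1.41 ± 0.05, adjusted p = 7e-07) and Plin2 2.58-fold (1.37 ± 0.06, adjusted p = 2.42e-06). The probe of Hilpda lies on chromosome 6 at 29225127 to 29225186. Fabp4 rose 1.67-fold (0.74 ± 0.07, adjusted p = 7.12e-04), and Abca1 and Abcg1 fell by 0.83 ± 0.08 and 0.81 ± 0.07 (adjusted p = 5.36e-04 and 2.65e-04). Within slide 2, from 2 arrays with FABP4 and 3 with both, the values were 1.49 for Cpt1a, 1.42 for Hilpda, 1.40 for Plin2, 0.80 for Fabp4, -0.77 for Abca1 and -0.76 for Abcg1, all past the threshold. In row 1 of slide 2, Plin2 had 8.34 and 8.35 on palmitic acid arrays 1 and 2 and 6.885 and 6.97 on FABP4 arrays 2 and 3. Cpt1a had 1.78 and 1.83 against 0.285 and 0.23. These arrays share a row but also differ in FABP4.

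In the presence of FABP4 limma called 670 genes, 504 up and 166 down, of which 21 rose and 1 fell by more than 1 on the log2 scale. Dok7 rose 3.57-fold (1.83 ± 0.07), and Lrrc32, which encodes a carrier of latent TGF-beta, 3.20-fold (1.68 ± 0.12, adjusted p = 1.19e-04). Csmd1 and Defb45 rose at least 2.75-fold and at least 6.32-fold from FABP4 arrays of which none was well above background for them. Pilra fell by 0.93 ± 0.06, with -0.78, -1.05 and 0.34 on its other probes (unadjusted p = 6.3e-05, 4.58e-04 and 0.119), N4bp3 by 0.98 ± 0.15 and the formyl peptide receptor gene Fpr1 by 0.74 ± 0.09.

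With the slide as a fixed block 590 genes passed (489 up, 101 down), 454 of them among the 670, and 56 of 65 named calls held. Within slide 2 alone 260 genes passed (216 up, 44 down), 231 of them among the 670, and 36 of the 65 held. In the fit with the block, FABP4 array 1 serves only to set the slide difference. Both fits therefore take this effect from the arrays of slide 2 and give the same sizes and list medians. They differ only in the error, so below they are not separate checks. The 29 calls that ended there kept their sign, at a median of 0.961 of their size (0.734 to 1.162), with an SE 1.14 times as large. Of the genes named here, Csf3, Soat1, Prdx1, Sqstm1, Ftl1, Ccnb1, Csf1r, Lgals3, Cx3cr1, Mmp9, Irf4 and Acta2 did not pass within slide 2, and Sqstm1, Ftl1, Irf4 and Acta2 did not pass with the slide as a fixed block either. Lgals3, Prdx1, Sqstm1 and Ftl1 did not pass after quantile normalization. The split of up and down calls moved with the scaling: it was 381 up and 329 down after quantile normalization and 426 and 360 with normexp and quantile normalization. With the 75th percentile over the probes detected on all arrays, chosen after seeing the data, it was 386 and 434, and with no scaling, chosen likewise, 67 and 92. Without FABP4 array 2 the count was 298, and without arrays 1, 2 and 3 of palmitic acid with FABP4 it was 247, 261 and 339. Of the 65 named calls, 36 held whichever array was left out. The median over all genes was 0.05, and it was 0.06 within slide 2 and with the slide as a block. Camera sets a list against the other genes, so the list medians below are to be read against these values and not against no change.

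Fatty acid synthesis and desaturation genes fell as a group by camera with FABP4 present (adjusted p = 1.51e-06), with adjusted p = 0.121 with an estimated correlation. Of 14 tested 4 fell, 0 rose and 10 did not pass, with 6 falls adjusted over the list alone. Acaca fell by 0.60 ± 0.05 and Scd2 by 0.72 ± 0.08 (adjusted p = 2.25e-04 and 8.82e-04), and both passed within slide 2 (-0.56 and -0.65). The list's median was -0.15, with adjusted p = 5.51e-06 with the slide as a block and 1.22e-05 within slide 2, where the median was -0.12. LXR and cholesterol efflux genes gave 2 falls, Abca1 and Abcg1, among 12, also adjusted over the list alone, and the list passed downward (median -0.11, adjusted p = 0.0133). That list had adjusted p = 0.121 with an estimated correlation, 0.0161 with the slide as a block, and 0.0147 within slide 2, where the median was -0.07. Lipid droplet genes gave 3 rises among 17, Plin2, Hilpda and the cholesterol esterifying enzyme gene Soat1 (0.37 ± 0.07), with 4 adjusted over the list alone. The call of Soat1 ended without array 1 of palmitic acid with FABP4 (adjusted p = 0.0748), without its array 2 (0.0639) and without FABP4 array 2 (0.0639). That list passed upward (median 0.08, adjusted p = 0.0344), with adjusted p = 0.321 with an estimated correlation, and its call ended with the slide as a block (adjusted p = 0.0524) and within slide 2 (adjusted p = 0.0575), where the median was 0.08 as well.

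With FABP4 present, fatty acid oxidation and PPAR targets gave 2 rises, Cpt1a and Plin2, among 20, also adjusted over the list alone. The list did not pass (adjusted p = 0.0900) but did within slide 2 (median 0.09, adjusted p = 0.0173) and with the slide as a block (adjusted p = 0.0134). Among 14 fatty acid binding and transport genes Fabp4 and Fabp3 rose (0.63 ± 0.07 for Fabp3), with 4 rises adjusted over the list alone, and the list gave adjusted p = 0.380. Of 24 cholesterol biosynthesis genes 2 rose and 1 fell, with 2 and 2 adjusted over the list alone. The list gave adjusted p = 0.0745, and passed upward within slide 2 (median 0.15, adjusted p = 0.00361) and with the slide as a block (adjusted p = 0.00251). Of 15 scavenger receptor genes 2 rose and 1 fell, with 5 and 1 adjusted over the list alone, and Cd68 rose by 0.35 ± 0.06 (adjusted p = 0.00906). That list passed upward (median 0.15, adjusted p = 0.0082), with adjusted p = 0.127 with an estimated correlation, 0.00294 with the slide as a block, and 0.00273 within slide 2, where the median was 0.16.

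Lysosome genes rose as a group with FABP4 present, with 5 rises and 0 falls among 27 and 12 rises adjusted over the list alone, and Gpnmb rose by 0.43 ± 0.05 (adjusted p = 0.0017). Their median was 0.15 (camera, adjusted p = 4.01e-06), with adjusted p = 0.121 with an estimated correlation, 6.13e-07 with the slide as a block, and 2.19e-06 within slide 2, where the median was 0.20. Glycolysis and hypoxia genes gave 9 rises and 0 falls among 30, with 18 rises adjusted over the list alone, among them Bnip3 with 0.89 ± 0.11, Ndrg1 with 0.70 ± 0.06 and the mitophagy gene Bnip3l with 0.42 ± 0.06. Its median was 0.19 (adjusted p = 1.34e-07), with adjusted p = 0.127 with an estimated correlation, 6.13e-07 with the slide as a block, and 2.19e-06 within slide 2, where the median was 0.17. Osteoclast genes gave 7 rises and 1 fall among 13, with 8 and 2 adjusted over the list alone. The fall was of Mmp9 by 0.64 ± 0.12 (adjusted p = 0.017), well above background on 2 of 3 arrays with both agents, and named after its values were seen. Dcstamp (Tm7sf4 on the array) rose by 0.66 ± 0.06, Atp6v0d2 by 0.62 ± 0.08 and Car2 by 0.41 ± 0.06. That list passed upward (median 0.35, adjusted p = 0.0101), with adjusted p = 0.127 with an estimated correlation, 0.0161 with the slide as a block, and 0.0217 within slide 2, where the median was 0.34.

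Unfolded protein response genes gave 6 rises and 0 falls among 21 with FABP4 present, with 9 rises adjusted over the list alone, and Dnajb9 rose by 0.67 ± 0.07 (adjusted p = 8.82e-04). The list's median was 0.10 (camera, adjusted p = 0.00565), with adjusted p = 0.321 with an estimated correlation, 1.82e-04 with the slide as a block, and 7.86e-04 within slide 2, where the median was 0.11. ATF4 and amino acid response genes gave 6 rises among 32, with 10 rises and 1 fall adjusted over the list alone (adjusted p = 0.382 for the list), among them Atf3 with 0.49 ± 0.04, Ppp1r15a with 0.64 ± 0.06, Slc3a2 with 0.48 ± 0.06 and Gdf15 with 0.88 ± 0.13. NRF2 genes gave 3 rises among 20, with 5 adjusted over the list alone, namely the peroxiredoxin gene Prdx1, the autophagy receptor gene Sqstm1 and the ferritin gene Ftl1 (0.24 to 0.28), none of which held whichever array was left out. Without array 2 of palmitic acid with FABP4 their adjusted p-values were 0.0602, 0.102 and 0.161. The NRF2 list passed upward (median 0.14, adjusted p = 0.0082), with adjusted p = 0.121 with an estimated correlation, 0.00251 with the slide as a block, and 0.00437 within slide 2, where the median was 0.16, and its call ended after quantile normalization (adjusted p = 0.0604). Of 12 heat shock genes 0 passed, with 1 rise and 2 falls adjusted over the list alone and 3674 of all genes at an unadjusted p under 0.05 in limma. The heat shock list passed downward (median -0.06, adjusted p = 0.0101), with adjusted p = 0.231 with an estimated correlation, 0.0161 with the slide as a block, and 0.0192 within slide 2, where the median was -0.01, and of its members Chordc1 had -0.19 ± 0.05 and Hspa8 0.17 ± 0.06, with -0.12 and 0.06 on its other probes.

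Cell cycle genes gave 4 falls and 0 rises among 34 with FABP4 present, with 13 falls adjusted over the list alone, and Ccnb1 fell by 0.30 ± 0.06 (adjusted p = 0.0208). That call ended without arrays 1, 2 and 3 of palmitic acid with FABP4 (adjusted p = 0.0616, 0.0874 and 0.0576). The list's median was -0.11 (camera, adjusted p = 4.79e-08), with adjusted p = 0.206 with an estimated correlation, 1.23e-05 with the slide as a block, and 2.05e-05 within slide 2, where the median was -0.07 and 0 members passed. Of 36 NF-kB genes 2 rose and 3 fell, with 4 and 8 adjusted over the list alone, and Csf2 fell by 0.68 ± 0.07 while Csf3 rose by 0.36 ± 0.06. The NF-kB list passed downward (median -0.02, adjusted p = 0.0289), with adjusted p = 0.437 with an estimated correlation, and its call ended with the slide as a block (adjusted p = 0.0524) and within slide 2 (median 0.01, adjusted p = 0.0606). Of 18 p53 target genes 3 rose, with 4 rises and 2 falls adjusted over the list alone (adjusted p = 0.876 for the list), among them Plk2 with 1.03 ± 0.08 and Mdm2 with 0.41 ± 0.06. Immediate-early and MAPK genes gave 2 rises and 2 falls among 19, with 3 and 3 adjusted over the list alone (adjusted p = 0.0628), with rises of Dusp4 by 0.47 ± 0.07 and Ier3 by 0.44 ± 0.07 and a fall of Dusp2 by 0.36 ± 0.05.

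Of the remaining lists with FABP4 present, interferon genes gave 2 rises among 35, Rsad2 and Igtp, also adjusted over the list alone. That list gave adjusted p = 0.0900 and passed upward within slide 2 (median 0.10, adjusted p = 0.0036) and with the slide as a block (adjusted p = 0.0011). Inflammasome genes gave 1 rise (Panx1) among 12, also adjusted over the list alone (adjusted p = 0.427), and alternative activation genes 1 rise (Irf4) among 12, with 4 rises and 1 fall adjusted over the list alone (adjusted p = 0.717). Macrophage identity genes gave 2 rises (Csf1r and Lgals3) and 1 fall (Cx3cr1) among 22, with 2 and 3 adjusted over the list alone (adjusted p = 0.169), and the other probes of Csf1r had 0.12 and 0.24 (unadjusted p = 0.176 and 0.0402). Rsad2, Igtp, Panx1 and Irf4 were named after their values were seen. The calls of Csf1r, Lgals3 and Cx3cr1 ended without each of the 3 arrays of palmitic acid with FABP4, at adjusted p-values of at most 0.0864, 0.0875 and 0.0943, and also without FABP4 array 2 (adjusted p = 0.0768, 0.0726 and 0.0840), and those of Csf1r and Cx3cr1 without FABP4 array 3 (adjusted p = 0.0571 and 0.0617). With a fixed slide block the call of Irf4 ended (0.41 ± 0.12 against 0.47 ± 0.11, adjusted p = 0.0979). Dendritic cell genes gave 0 calls among 9 (adjusted p = 0.524), and oxidative phosphorylation genes 0 among 29, with adjusted p = 0.524 upward, and downward after quantile normalization (adjusted p = 0.00913). The neutrophil and adipocyte lists had 0 members past the threshold, and 1 fibroblast gene, Acta2, named after its values were seen, fell by 0.24 ± 0.06 (adjusted p = 0.0396), a call that ended with the slide as a block at the same size (-0.24 ± 0.06, adjusted p = 0.0769).

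**Figure D3:**
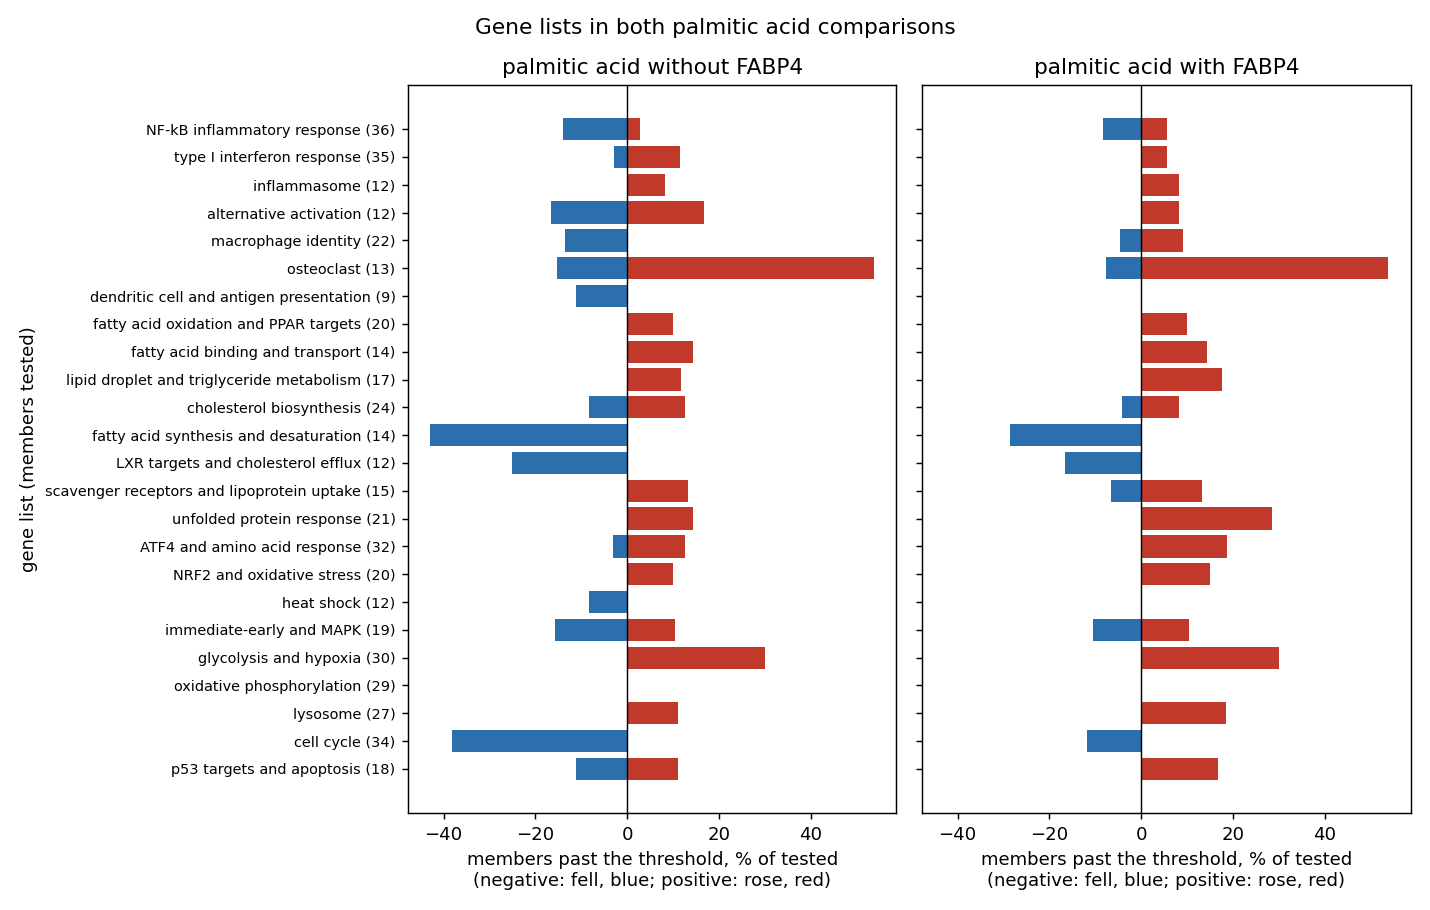
Share of each gene list's tested members past the threshold (x axis, percent, falls to the left in blue and rises to the right in red) for the 24 lists tested (y axis, members tested in brackets) under palmitic acid without FABP4 (left) and with FABP4 (right). Osteoclast genes gave 7 rises among 13 in both panels, glycolysis and hypoxia genes 9 among 30 in both, and cell cycle genes 13 falls without FABP4 and 4 with it.

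Whether the effect of palmitic acid differed with FABP4 was tested as the interaction. Limma called 0 genes, with 1218 at an unadjusted p under 0.05 and a lowest adjusted p of 0.30, so the difference between 1515 and 670 calls does not show that any gene responded differently. For Fabp4 the interaction was 0.18 ± 0.11 (adjusted p = 0.723), and for Adm it was -0.81 ± 0.29 (adjusted p = 0.680). Among genes named by rule, which have an official symbol, the smallest p-values belonged to Lrrc14 (-0.44 ± 0.08), Fam107a (0.63 ± 0.11), Suox (0.44 ± 0.08) and Prpf38b (0.53 ± 0.10) and to Csmd1, a dim gene, each with adjusted p = 0.426, and to Cgref1 (adjusted p = 0.481), which was not well above background on any control array. No list passed (lowest adjusted p = 0.657). In data simulated with 200 changed genes, an interaction was recovered for 50.0% of them at 1.5-fold and for 77.5% at 2-fold, but for 0% at the smallest change simulated. Fitted with a slide block, 37 genes passed (33 up, 4 down), and without FABP4 array 1 there were 5, without control array 1 there was 1, without array 3 of palmitic acid with FABP4 there were 2, and with no scaling 3.

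The palmitic acid comparisons without and with FABP4 share no arrays, and 456 genes passed in both, all in the same direction. Of these 326 rose, where 24.6 would be expected of independent lists, and 130 fell, where 6.2 would be expected. Among the genes called without FABP4 92.1% had the same sign with it, and among those called with FABP4 97.6% had the same sign without it. The median ratio of the effect with FABP4 to that without was 0.991 over the shared genes. Choosing genes that passed in both comparisons favours a ratio near 1. Across all 17596 genes, which are not independent replicates, Pearson's r was 0.470 and Spearman's rho 0.557. Both comparisons also carry a slide difference in the same direction, since the controls and FABP4 array 1 lay on slide 1 and all arrays with palmitic acid on slide 2, and the expected counts leave this out. The expected counts also leave out that both comparisons use the same estimate of each gene's spread. Of the 456 genes, 189 also passed for palmitic acid with FABP4 within slide 2.

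**Figure D4:**
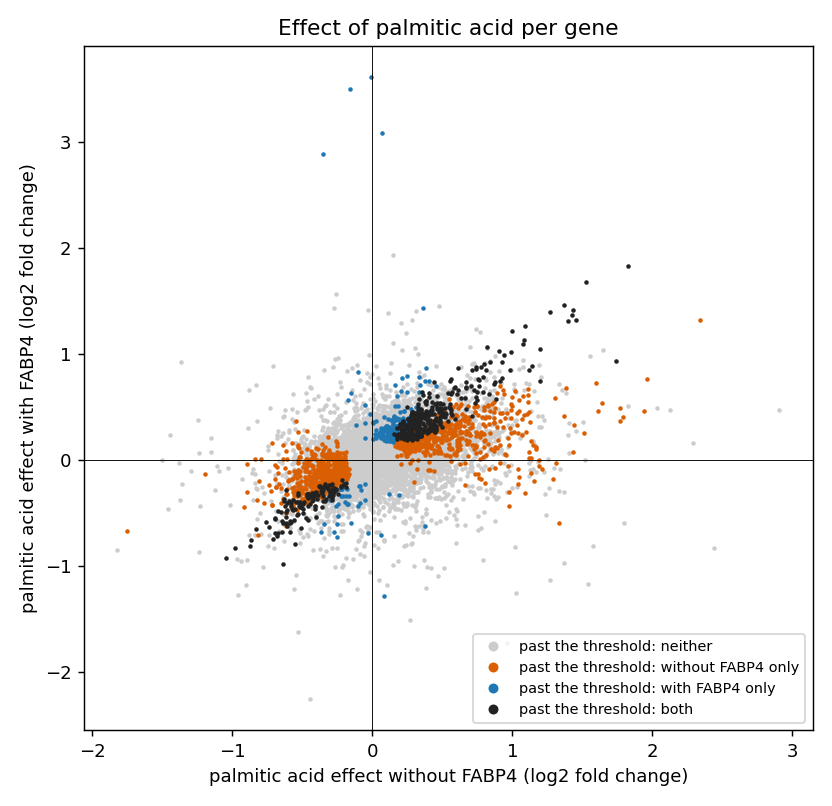
Log2 fold change of every tested gene under palmitic acid without FABP4 (x axis) and with FABP4 (y axis), colored by the comparison in which it passed the threshold. The 456 genes past the threshold in both (black) all lie in the upper right or lower left quadrant.

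Added FABP4 without palmitic acid lowered the splicing gene Prpf38b and raised 2 long intergenic RNAs, but 0 of these 3 calls held when any array other than FABP4 array 1 was left out. They also ended with the slide as a random block and with normexp. Limma called 3 genes, of which 2 rose and 1 fell, with 1273 at an unadjusted p under 0.05. The fall was of Prpf38b, which encodes a pre-mRNA splicing factor, by 0.56 ± 0.07 (adjusted p = 0.0473), from a probe on chromosome 3 at 108708070 to 108708129. The rises were of probes for long intergenic RNAs on chromosome 5 at 52999234 to 52999293 and chromosome 17 at 84489156 to 84489215, by at least 1.93-fold and at least 1.88-fold from controls that were not well above background. These 2 were outside the naming rule and chosen after their values were seen, and both were also called upward for palmitic acid without FABP4 (adjusted p = 0.00132 and 0.00124), against the same dim controls. Prpf38b was likewise called downward for palmitic acid without FABP4 (-0.31, limma adjusted p = 0.02045), against the same controls on slide 1. The call of Prpf38b held without FABP4 array 1 (adjusted p = 0.0297), a fit that compares entirely across the slides. It ended without each of the other arrays, at adjusted p-values from 0.0771 without palmitic acid array 2 to 0.221 without control array 3. Over all settings run for it the adjusted p lay between 0.0297 and 0.342. It also ended with the slide as a fixed block (-0.54 ± 0.10, adjusted p = 0.0542), as a random block (-0.55 ± 0.08, 0.206) and within slide 1 (-0.54 ± 0.11, 0.342). Slide 1 holds 1 FABP4 array, so the fixed block and the fit within slide 1 both set that array alone against the controls and assume that it varies like the other groups.

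Fabp4 itself differed by 0.00 ± 0.07 with the added protein (adjusted p = 0.999), with a 95% confidence interval from -0.16 to 0.17. Genes named by rule that did not pass included the orphan receptor gene Nr4a1 (-0.43 ± 0.09, adjusted p = 0.366), Csf2 (0.19 ± 0.07, adjusted p = 0.597) and Cpt1a (-0.14 ± 0.06, adjusted p = 0.658). No list passed for FABP4 without palmitic acid (lowest adjusted p = 0.395), while with the slide as a block the cholesterol biosynthesis and cell cycle lists passed upward (adjusted p = 0.00606 each), again from FABP4 array 1 alone against the controls. The groups did not overlap for 1834 genes, 10.4% of those tested, and 10% is what chance gives for 3 arrays against 3. In simulated data this comparison recovered 65.0% of genes changed 1.5-fold and 89.0% of those changed 2-fold. The count was 103 with the slide as a fixed block, from that array alone (20 up, 83 down), 0 with it as a random block and 0 within slide 1. Without FABP4 array 1 it was 59, without control array 1 it was 1, and without each of the other 10 arrays it was 0. Without FABP4 array 1 the remaining FABP4 arrays lay on slide 2 and all controls on slide 1. Those 59 calls therefore cannot be told apart from a slide difference.

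Added FABP4 in the presence of palmitic acid, compared within slide 2, gave 0 calls in limma, with 1034 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.378. Fabp4 changed by 0.19 ± 0.07 (adjusted p = 0.806), which did not pass. Simulated changes of 1.5-fold and 2-fold were recovered for 69.0% and 90.5% of genes here. The groups did not overlap for 2547 genes, 14.5% of those tested, where chance gives 10%. FABP4 was largely mixed with the row on the slide here, so this excess cannot be credited to FABP4. In limma, 1511 genes had an unadjusted p under 0.05 without palmitic acid array 3, the only one in row 2. Without palmitic acid arrays 1 and 2 there were 631 and 818. Fitting the 8 arrays of slide 2 alone also gave 0 genes, and without control array 1 the count was 1 and without array 3 of palmitic acid with FABP4 it was 2. Csmd1 and Defb45 lay at least 2.70-fold and at least 5.68-fold above arrays on which they were not well above background, but did not pass (adjusted p = 0.378 and 0.806).

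As groups, genes of oxidative phosphorylation and of cholesterol biosynthesis were slightly higher with FABP4 in the presence of palmitic acid by camera, with adjusted p = 0.946 for both with an estimated correlation, and 0 of their members passed, over all genes or adjusted over the list alone. Of 29 oxidative phosphorylation genes 28 had positive values, with a median of 0.06 (camera, adjusted p = 0.00207), among them the respiratory chain subunit genes Uqcrq (0.14 ± 0.05) and Ndufa4 (0.17 ± 0.07). Of 24 cholesterol biosynthesis genes 22 were positive, with a median of 0.09 (adjusted p = 0.0166), among them Mvk (0.22 ± 0.07) and Ebp (0.19 ± 0.06), which encode enzymes of the pathway. The other probes of Uqcrq and Mvk had 0.05 and 0.01 (unadjusted p = 0.506 and 0.913). Both lists gave adjusted p = 0.288 with fry, and both calls ended after quantile normalization (adjusted p = 0.383 and 0.105). Within slide 2 the adjusted p-values were 0.00687 and 0.0168 at the same medians, and with the slide as a block 0.00227 and 0.00855. This comparison already lay within slide 2, so neither fit could move its medians. It also largely mixes FABP4 with the row on the slide, and an effect of position was not tested. The median over all genes was 0.03.

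Averaged over both arms, FABP4 gave 0 calls in limma, with 938 genes at an unadjusted p under 0.05 and a lowest adjusted p of 0.416, that of Prpf38b (-0.30 ± 0.05). Fabp3 had 0.20 ± 0.05 (adjusted p = 0.729) and Fabp4 0.09 ± 0.05 (adjusted p = 0.909). Simulated changes were recovered for 85.0% of genes at 1.5-fold and for 54.5% at the smallest change simulated. The oxidative phosphorylation and cholesterol biosynthesis lists passed upward (adjusted p = 0.0164 each), with adjusted p = 0.978 each with an estimated correlation and 0.871 each with fry. After quantile normalization the oxidative phosphorylation call ended (adjusted p = 0.148), and the interferon and ATF4 lists passed downward (adjusted p = 0.00375 and 0.00408). The cell cycle list also passed upward with the slide as a block (adjusted p = 0.0016). A slide block gave 39 genes (8 up, 31 down), while without FABP4 array 1 there were 10, and without array 3 of palmitic acid with FABP4 there were 2. Across all genes, which are not independent replicates, the effects of FABP4 in the 2 arms had Pearson's r of -0.044 and Spearman's rho of -0.042. A list's median, mean and test differed in sign for 3 to 9 of the 24 lists per contrast, and none of those lists had passed.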

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

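The 75th percentile over detected probes, no scaling and the list tests within slide 2 were tests chosen only after the results were seen. For palmitic acid without FABP4 (1515 genes), the count was 3055 with no scaling, 513 with no filter on dim probes, 138 and 191 with the slide as a fixed and a random block, 32 with replicate block and slide block together, and 72 with a minimum log2 change of 1. Leaving out each array gave 655 to 2716. For palmitic acid with FABP4 (670 genes), it was 159 with no scaling, 185 with no filter, 260 on slide 2, 94 from only the 2 groups compared, 1138 with trended and robust moderation, 22 with the minimum change, and 247 to 601 leaving out each array. For FABP4 without palmitic acid (3 genes), it was 0 with normexp and the 75th percentile, with normexp and quantile normalization, with the percentile over detected probes, with probes above background on all 12 arrays, with the mean of probes, with a random slide block, on slide 1 and from only the groups compared. It was 1 with no filter, 1 with every probe tested, 103 with a fixed slide block, which leaves 1 FABP4 array in that arm, and 0 to 59 leaving out each array. For FABP4 with palmitic acid (0 genes), it was 1 with every probe tested, 1 with trended and robust moderation, and 0 to 2 leaving out each array. The interaction (0) gave 3 with no scaling, 37 with a fixed slide block and 0 to 5 leaving out each array, and the average effect of FABP4 (0) gave 39 with a fixed slide block and 0 to 10. A minimum change lowers the count by its construction, and 1 slide or 2 groups leave fewer arrays in the fit. For the other settings the cause was not tested. Counts under the settings not given here lay within 1.5 times of the first.

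Numbers shared by replicates across groups gave little sign of pairing the arrays. Same-numbered arrays deviated together with r from -0.077 to 0.168 over 18 pairs, 1 of them above 0.1, and 3 of 12 arrays correlated best with their own number. Within the FABP4 group the deviations also carry the slide difference, which could hide a pairing, so a pairing is not excluded. With a replicate block the counts were 0 for FABP4 without palmitic acid, 1339 and 408 for palmitic acid without and with FABP4, and with replicate block and slide block together 32, 32 and 257, with 16 for the interaction and 17 for the average effect of FABP4.

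The cell cycle list, downward without passing for FABP4 without palmitic acid (adjusted p = 0.926), passed upward with the slide as a block (adjusted p = 0.00606), and over its alternatives the adjusted p ran up to 0.995. The oxidative phosphorylation list, upward without passing for palmitic acid with FABP4 (adjusted p = 0.524), passed downward after quantile normalization (adjusted p = 0.00913), with adjusted p up to 0.835 over its alternatives, and the cause of both was not tested. With an estimated correlation 8 list calls for palmitic acid without FABP4, 12 with it, 2 for FABP4 with palmitic acid and 2 for its average effect ended, which is every list call made on all 12 arrays with the 75th percentile and no block. With fry, which does not compare a list with other genes, the NF-kB and heat shock list calls for palmitic acid with FABP4 (adjusted p = 0.264 and 0.0531), both for FABP4 with palmitic acid and both for its average effect ended, while 6 lists more passed for palmitic acid without FABP4 and 4 more with it, in the direction camera gave. With quantile normalization the interferon and ATF4 lists passed downward for FABP4 with palmitic acid (adjusted p = 0.00104 and 0.0182). Of the named calls, 45 of 70 without FABP4 and 36 of 65 with it held whichever array was left out, and 67 and 57 held after quantile normalization. A replicate block ended 1 list call for palmitic acid with FABP4 and changed no list call in the other contrasts. Leaving out arrays was not run for the list tests, nor were scalings other than quantile normalization. Dim probes limit what can be seen: over 50% of the spots on each array were not well above background, and genes above it on all arrays of no group were not tested.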

Other observations

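Of the tests here, those of the interaction with the slide as a block, of array FABP4 1 against the arrays with palmitic acid, and both on glycolysis and hypoxia genes were chosen only after the result was seen, as were the genes named in the next paragraphs.

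In all, 189 genes passed without FABP4, with FABP4 and within slide 2 alone, 157 up and 32 down, and some of those not yet named are given here. Hbegf, an EGF receptor ligand, rose by 1.00 ± 0.07 without FABP4 and 1.22 ± 0.07 with it (SE, n = 3 per group, limma adjusted p = 1.53e-04 and 4.95e-05), and by 1.16 within slide 2. The neuropeptide gene Npy rose by 0.99 ± 0.15 and 1.02 ± 0.15, and Angpt2, a ligand of the endothelial receptor Tie2, by 0.84 ± 0.14 and 0.92 ± 0.14. Plau, the urokinase gene, rose by 0.73 ± 0.11 and 0.54 ± 0.11.

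The lipid-sensing receptor gene Trem2 rose by 0.49 ± 0.06 in both comparisons, and by 0.55 within slide 2 (adjusted p = 0.0147). Sphk1, which makes sphingosine 1-phosphate, rose by 0.91 ± 0.07 and 0.74 ± 0.07, the enolase gene Eno2 by 0.94 ± 0.10 and 0.99 ± 0.10, and the hexokinase gene Hk3 by 0.56 ± 0.05 and 0.45 ± 0.05. Genes that fell were the scaffold gene Akap12 by 0.67 ± 0.07 and 0.69 ± 0.07, the myeloid kinase gene Fgr by 0.70 ± 0.06 and 0.55 ± 0.06, Id1, an inhibitor of bHLH factors, by 0.65 ± 0.08 and 0.57 ± 0.08, and the adenosine receptor gene Adora2b by 0.62 ± 0.07 and 0.54 ± 0.07. Leaving out arrays was not run for these genes.

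More genes passed for palmitic acid without FABP4 (1515) than with it (670), and the former comparison lies across the slides. Over 560 genes called without FABP4 and at an unadjusted p of 0.05 or more with it, the slide difference within the FABP4 group was 0.398 of the palmitic acid effect (95% interval 0.359 to 0.432), with the same sign at 78.2% of them, and 0.147 over the other 955 called genes. That share lies between the bounds set for and against the slide as the cause, and the FABP4 arrays also enter the choice of both sets, so it decides nothing and a difference between the slides stays open. A different response without FABP4 also stays open, since the interaction gave 37 genes with the slide as a block and 0 without. Both rest on 1 FABP4 array on slide 1, so they cannot be told apart here. With the block, the interaction takes the effect of FABP4 without palmitic acid from that array alone. Its calls may therefore come from that array standing apart, and do not by themselves show a different response. The 95% interval above comes from resampling genes and not arrays, so it leaves out the spread between arrays.

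A fit with the slide as a block called 103 genes for FABP4 without palmitic acid, among them falls of Prmt1 by 1.60 and Hmox1, which encodes heme oxygenase, by 1.23, and a rise of Anp32a by 1.53. An effect of FABP4 in both arms that the slide difference hides is argued against: within slide 2 the effect of FABP4 with palmitic acid was -0.004 of the blocked effect (95% interval -0.029 to 0.021), with the same sign at 42.7% of the genes, though an effect confined to cells without palmitic acid stays open. The fit with the slide as a block sets array FABP4 1 alone against the controls, so these genes were chosen by its departure from them. Prmt1 lay at 4.02 against 5.46 to 5.67, and Hmox1 at 4.10 against 5.16 to 5.46, on the other 11 arrays. The arrays with palmitic acid alone differed from the controls by -0.027 of the blocked effect (95% interval -0.096 to 0.035), which is consistent with array FABP4 1 standing apart for reasons of its own, in a test that shares its controls with the pattern. What sets that array apart was not tested. Both 95% intervals come from resampling genes and not arrays, so they leave out the spread between arrays.

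Glycolysis and hypoxia genes were higher with palmitic acid in both comparisons by camera, although with an estimated correlation the list gave adjusted p = 0.127 with FABP4 and 0.272 without it. Within slide 2 their median was 0.17 (camera, adjusted p = 2.19e-06, 30 genes), so a difference between the slides is argued against as the cause with FABP4, and stays open for the size without it. The median exceeded that over all genes in the same fit (0.06) by 0.11, which restates the camera call and tests nothing more. A response of these genes to palmitic acid, which the design names, stays open as a hypothesis. Oxygen in the cultures was not measured here. The groups compared within slide 2 also lay in different rows of it, and an effect of position was not tested.

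For the comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05. The real split gave 1515 genes for palmitic acid without FABP4 and 670 with it, 1 of 10 splits each, and the highest other gave 0 in both. For FABP4 with palmitic acid the real split gave 0 and the highest other 0, and with a real count of 0 all 10 of 10 splits must give as many, which tests nothing. For FABP4 without palmitic acid it gave 3, and 2 of 10 splits gave as many: setting control arrays 1 and 3 and FABP4 array 1 against the rest gave 10, which points to a structure of the samples. The 4 splits with both slide 2 arrays on one side gave 3 (the real one), 10, 1 and 1, the other 6 gave 0, and the count with the slide as a block was 103. For the interaction and the average effect of FABP4, both 0, the same holds for all 100 assignments drawn, with highest others of 2 and 1, so the splits say nothing about chance there.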
